A study of Rattus norvegicus with 30 samples.

How the data were processed

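Gene expression in lung was measured on 30 Agilent arrays with 62976 spots each, 1 array per rat. Per the labels' protocols, 200 ng of total RNA from each rat, with an RNA integrity number above 7, was labelled with Cy5, and a common reference RNA was labelled with Cy3. The labels disagree on that reference, since the labelling protocol names a mouse reference RNA and the second channel's source names a rat reference RNA made from 14 cell lines. The reference is shared by all arrays and drops out of every difference between groups. The labels also give the nanoparticle as the treatment of the rats with a dose of 0 mg/m3, which were handled here as the air controls that the protocol describes.

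Each rat's deposited scanner output holds spot intensity values made with Agilent Feature Extraction, per the file headers. The intensity columns used were the median pixel brightness of each spot and of its local background in both channels. Processed signals, already corrected for background and dye by Feature Extraction per the file headers, and the scanner's flags for background, saturation and outlying spots were also deposited. The authors' deposited value table gives 1 log2 ratio per probe and array. How those ratios were made after Feature Extraction is not given in the sources used here. Set against the scanner values over probes of 1 array, which are not independent replicates, the authors' log2 ratios correlated at 0.997 to 1.000 with loess-normalized log2 Cy5 over Cy3 without background correction, and the medians of their columns lay between -0.0314 and -0.00539. Their scale and direction were therefore taken as log2 of sample over reference, centred near 0; the method itself stays unknown.

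Signals were corrected with the normexp model (offset 50) on the median spot and median local background intensities. The plan had named mean spot intensities, which are not among the columns used here. Log2 ratios of Cy5 over Cy3 were normalized by loess within each array, with control spots (4259 of 62976, or 6.76%) and outlier-flagged spots given no weight. Flagged spots were then left out, saturated spots were kept, and spots of 1 probe were averaged. A probe was kept when its Cy5 signal was well above background on at least 5 of the 30 arrays, which left 20852 of 30367 probes. Probe accessions were matched without version numbers to a RefSeq gene table of assembly GRCr8, which named 18005 probes by 15168 symbols and left 12362 probes under the files' own identifiers. The arrays' own coordinates refer to an older assembly, rn4, so no coordinates are given. The probe with the highest mean intensity stood for each gene, giving 18420 genes, of which 11331 had a symbol and 7089 did not. Of the 90 genes named by rule, 16 had several probes, and none of those had a probe past the threshold in the opposite direction at the high dose on day 6.

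Group means of all 6 groups were fitted together with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), and 9 contrasts were tested with Benjamini-Hochberg adjustment within each contrast at an adjusted p of 0.05. Adjusted p-values and standard errors (SE) are from this fit unless stated otherwise. The replicates are separate rats, 5 per group, and their number limits the precision: the median SE of a log2 fold change between groups was 0.115, and 0.163 for a difference of effects between days. Data were simulated for the high dose on day 6 (18399 genes). The fit recovered 35 of 67 genes changed by 0.5 (log2), 61 of 67 by 1 and 66 of 66 by 2. There 6 of 168 called genes were unchanged ones. With no simulated low dose change limma called 0 genes. Camera there called 10 of 10 shifted and 0 of 30 unshifted lists. Correlation between real genes is untested and far more of them passed, so these rates do not carry over.

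The groups, the tests, 31 gene lists and the rule for named genes were chosen before the data were examined. The rule took, among genes with a symbol past the threshold whose 5 exposed and 5 air values did not overlap, the 12 largest increases and 6 largest decreases at the high dose on day 6, and up to 6 increases and 4 decreases in each other comparison of exposed rats with air. To these it added the 2 members of each list with the smallest p at the high dose on day 6, and a fixed panel in which Mt1a is measured under its current symbol Mt1 and Cxcl3, Mki67 and Top2a were not measured under those names. A further gene taken by the rule is not reported here and is left out of the counts of named genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists of a comparison, with the count of members past the threshold over all genes and adjusted over the list alone. Camera with an estimated correlation, and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives. Inflammation and cell proliferation are named in the series title, so the lists on these themes were not blind to the study. Means of a list per rat were compared with two-sided exact permutation tests, whose smallest possible p with 5 rats per group is 0.00794.

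The 30 arrays lie on 4 slides, each holding several groups; the third slide holds no air array of day 28. Slide entered the fit as a fixed block in an alternative, and differences were recomputed within each slide. Where a gene's probes were not well above background on any array of a group, its fold change is approximate. It compares normalized Cy5 means with the dimmest signals counted as above background, without sampling error. No dyes were swapped, so dye bias is possible. Fitted log ratios, made with the offset of 50, are on another scale. For Cxcl11, Mmp7, Orm1 and Tac1 at the high dose on day 6 they were smaller in size (2.73, 3.36, 3.15 and -3.31 on the log2 scale). Further alternatives were Feature Extraction's processed signals, loess without background correction, median centring of each array, Cy5 alone with quantile normalization, the authors' table, other filters on dim probes, other handling of several probes per gene, array weights, a variance trend with robust estimation, a fit of the compared groups only, a 1.5-fold minimum and leaving out each rat in turn. Adding Aquantile normalization after loess leaves log ratios as they are, so it tests nothing here. Both doses share their air rats, so correlations and overlaps between doses were set beside 100 simulations of unchanged groups against the same controls and beside controls split 2 and 3. Python 3.11.15 with matplotlib 3.10.9 drew the figures.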

Results

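Lung RNA was profiled in 30 adult male Wistar rats, a common outbred laboratory strain, after nose-only inhalation of copper oxide nanoparticles or of air on 5 days. Air, 3.3 mg/m3 (low dose) and 13.2 mg/m3 (high dose) were each sampled 1 day after the exposures ended (day 6) and after 22 days without exposure (day 28), with 5 rats in each of the 6 groups. Each rat gave 1 array. The median Cy5 intensity of the arrays, which is the signal of the lung RNA, lay between 216 and 432, and 59.5% to 68.4% of the probes were well above background. Log ratios of arrays from 1 group correlated at 0.918 to 0.982 across probes, which are not independent replicates. The comparisons ask what inhaled particles changed in the lung, how the change depended on dose, and whether it persisted.

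The day after the last exposure, lungs of high dose rats held many times more RNA of chemokines that attract monocytes than lungs of air rats. Ccl12, Ccl2 and Ccl7, all of them monocyte attractants, were 77.8-fold, 52.1-fold and 47.3-fold higher, at log2 fold changes of 6.28 ± 0.34, 5.70 ± 0.42 and 5.56 ± 0.31 (SE, n = 5 rats per group; adjusted p = 4.84e-14, 2e-11 and 1.12e-13). Cxcl10, a chemokine induced by interferon, rose by 4.73 ± 0.27, and Lcn2, an iron-sequestering defence protein, and the beta-defensin Defb5 rose by 4.63 ± 0.33 and 4.77 ± 0.44. All 5 exposed rats lay above all 5 air rats for each of these 6 genes. Slc26a4, an anion exchanger, rose by 3.68 ± 0.13, Prss30, a serine protease, by 3.97 ± 0.33, and the interferon-induced genes Ifi27l2b and Slfn4 by 4.35 ± 0.25 and 3.93 ± 0.31. Large decreases were in Serpinb10 (-3.43 ± 0.35) and in the phospholipase Pla2g2d (-2.46 ± 0.24). Tac1, which encodes substance P, was about 10.6-fold lower in normalized Cy5 at its brightest probe (adjusted p = 8.04e-10). In high dose rats the signal of that probe was not well above background. A second Tac1 probe fell less (-1.22, adjusted p = 3.59e-07). The neutrophil chemokine receptor Cxcr1 (-2.41 ± 0.31) and the endothelial gene Esm1 (-2.35 ± 0.26) also fell.

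Inflammatory groups rose together at the high dose on day 6. Of 24 measured chemokines, 16 rose and 3 fell (17 and 3 adjusted over the list alone; list adjusted p = 2.94e-08). Among them Ccl17, a T cell attractant, rose by 3.28 ± 0.15 and Cxcl1, a neutrophil attractant, by 2.83 ± 0.22. Cxcl11 was about 8.29-fold higher in normalized Cy5, its signal in air rats being not well above background. Of 15 cytokine genes, 8 rose and 1 fell over all genes and over the list alone (adjusted p = 0.000826). Spp1, osteopontin, rose by 3.06 ± 0.24 and Osm, a cytokine of the interleukin 6 family, by 0.90 ± 0.11. Among 18 acute phase and secreted defence genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, list adjusted p = 3.83e-07). Orm1, an acute phase glycoprotein, was about 12-fold higher in normalized Cy5. These 3 lists kept an adjusted p under the threshold with an estimated correlation (0.0259, 0.0469 and 0.0259). Of 17 complement genes 13 rose (14 rose and 1 fell adjusted over the list alone, list adjusted p = 3.61e-07, adjusted p = 0.0605 with an estimated correlation). C3, the central complement component, rose by 2.75 ± 0.20 and the regulator Cfi by 3.07 ± 0.25. Within the 4 slides the mean shift was 1.38 to 1.82 for chemokines, 0.56 to 0.79 for cytokines, 1.27 to 1.66 for acute phase genes and 0.86 to 1.22 for complement.

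Markers of several leukocytes rose. Neutrophil markers gave 9 of 14 higher and 2 lower (the same adjusted over the list alone, list adjusted p = 0.00719, adjusted p = 0.0993 with an estimated correlation). S100a9, a calcium-binding protein abundant in neutrophils, rose by 3.50 ± 0.36 and the decoy receptor Il1r2 by 2.38 ± 0.15. Macrophage and monocyte markers gave 17 of 26 higher and 1 lower (the same adjusted over the list alone, list adjusted p = 0.000236, adjusted p = 0.194 with an estimated correlation). Mmp12, the macrophage elastase, rose by 4.04 ± 0.17 and Siglec1, a macrophage sialic acid receptor, by 3.67 ± 0.31. T cell markers gave 13 of 17 higher and none lower (13 adjusted over the list alone, list adjusted p = 0.000103, adjusted p = 0.134 with an estimated correlation). The costimulatory receptor Icos rose by 1.75 ± 0.16 and Cd2 by 0.74 ± 0.12. Antigen presentation and dendritic cell markers gave 10 of 14 higher (10 adjusted over the list alone, list adjusted p = 6.08e-05, adjusted p = 0.142 with an estimated correlation). The class II loading genes RT1-DMa and RT1-DMb rose by 1.67 ± 0.13 and 1.24 ± 0.13. B and plasma cell markers did not shift as a list. Of 11, 3 rose, including Blnk (1.24 ± 0.13) and Mzb1 (0.68 ± 0.17). The median was -0.06 while the mean was 0.14 and the test pointed upward (adjusted p = 0.734). NK and cytotoxic cell markers did not shift either (3 of 13 rose, adjusted p = 0.346), although Ctsw and Klrk1 rose by 0.97 ± 0.19 and 0.99 ± 0.18. Of 13 mast cell and eosinophil markers 2 fell, the transcription factor Gata2 (-1.45 ± 0.23) and the stem cell factor receptor Kit (-0.74 ± 0.19), and the list did not shift (adjusted p = 0.248). For these 3 lists the counts adjusted over the list alone were equal to those over all genes. Mean shifts within slides were 0.73 to 0.81 for neutrophil, 0.38 to 1.21 for macrophage, 0.40 to 0.68 for T cell and 0.61 to 0.77 for antigen presentation markers.

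Markers of the thin gas-exchange cells of the alveolus fell at the high dose on day 6. Of 13 alveolar type I cell markers 10 fell and none rose (10 adjusted over the list alone, list adjusted p = 8.1e-06, adjusted p = 0.0968 with an estimated correlation). Cav1, the main protein of caveolae, was lower by -1.6 ± 0.14 and the cytochrome Cyp4b1 by -1.48 ± 0.23. Of 13 markers of alveolar type II cells, which make surfactant, 5 rose and 1 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.114; 0.0214 with slide as a block). The protease Ctsh rose by 2.23 ± 0.29, the transcription factor Etv5 fell by 0.93 ± 0.14 on the log2 scale, and surfactant protein gene Sftpc was at -0.08 ± 0.24 (adjusted p = 0.823). Endothelial markers fell as a list (6 of 17 lower and 2 higher, 8 and 2 adjusted over the list alone, list adjusted p = 0.0149, adjusted p = 0.518 with an estimated correlation). The receptor Flt1 was at -0.67 ± 0.11, while the leukocyte adhesion molecule Sele rose by 0.90 ± 0.13. Extracellular matrix genes rose (12 of 21 higher, 2 lower, the same adjusted over the list alone, list adjusted p = 0.0125, adjusted p = 0.25 with an estimated correlation). Cthrc1 rose by 2.35 ± 0.24 and Tgfbi by 1.94 ± 0.16. Matrix proteases and their inhibitors rose (12 of 18 higher, none lower, 12 adjusted over the list alone, list adjusted p = 7.9e-05, adjusted p = 0.102 with an estimated correlation). Mmp7, matrilysin, was about 11.9-fold higher in normalized Cy5. By slide the mean shift was -0.92 to -0.42 for type I, 0.31 to 0.78 for type II and -0.36 to 0.02 for endothelial markers, 0.27 to 0.71 for matrix genes and 0.53 to 1.20 for proteases.

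Airway and heart muscle markers varied with a single air rat. Club and goblet cell markers had 3 of 16 higher, including Cldn10 (1.30 ± 0.21) and the mucin Muc20 (0.77 ± 0.11), and 3 lower (4 and 3 adjusted over the list alone). Their median was -0.17, the mean 0.16 and the test pointed downward (adjusted p = 0.986). Without air rat 4 of day 6 their median was 0.48 and the test pointed upward (adjusted p = 0.237), and the median of ciliated markers turned from -0.10 to 0.20 (adjusted p = 0.602). The secretoglobin Scgb1a1 was at -0.25 ± 0.14 (adjusted p = 0.156) and passed with Cy5 alone (-1.28) and in the authors' table (-0.40). Ciliated cell markers did not shift (1 of 12 higher, Tekt2 at 1.21 ± 0.12, and 1 lower, Tppp3 at -1.07 ± 0.18, over all genes and over the list alone, list adjusted p = 0.613). Basal and injured epithelium genes did not shift (1 of 17 higher and 5 lower, 2 and 5 adjusted over the list alone, list adjusted p = 0.213). Hbegf, an epidermal growth factor ligand, fell by 0.53 ± 0.10 on the log2 scale. Tp63 was at -0.47 ± 0.11, a call that ended when its probes were averaged (-0.14, adjusted p = 0.452). Air rat 4 of day 6 stood apart, with a mean of heart muscle genes of 4.71 against -0.75 over the other 4 air rats, of club and goblet markers of 4.16 against 2.37, and of ciliated markers of 3.03 against 1.86. By limma 0 of 12 heart muscle genes passed at the high dose (2 at an unadjusted p under 0.05, 0 adjusted over the list alone). The list fell nonetheless (adjusted p = 0.0385, adjusted p = 0.616 with an estimated correlation), with slide differences from -5.52 to 0.05, and did not pass without that air rat (adjusted p = 0.602, median -0.21 in place of -1.43; an alternative chosen after seeing the data). Actc1, cardiac actin, was at -1.26 ± 0.60 (adjusted p = 0.102) and Ryr2, a calcium channel of heart muscle, at -0.21 ± 0.09 (adjusted p = 0.0558). Cox8b, a muscle form of a respiratory chain subunit, fell by 2.75 ± 0.37 on the log2 scale, and stood at -2.20 without that rat. Without it 6344 genes passed at the high dose on day 6. Erythroid genes fell (4 of 7 lower, 5 adjusted over the list alone, list adjusted p = 0.0149, adjusted p = 0.194 with an estimated correlation). The hemoglobin genes Hbb and Hbb-b1 were at -0.90 ± 0.23 and -1.07 ± 0.27, Hbb at -0.66 with adjusted p = 0.0594 at its second probe. Their list mean shifted within slides by -0.96 to -0.35.

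Genes of cell division, of the interferon response and of sterol synthesis rose as groups at the high dose on day 6. Of 25 mitosis genes 24 rose (24 adjusted over the list alone, list adjusted p = 6.37e-22). The kinase Cdk1 rose by 2.59 ± 0.13 and Cdca3 by 2.52 ± 0.16. Of 25 genes of DNA replication 23 rose (25 adjusted over the list alone, list adjusted p = 2.42e-14). Rrm2, a subunit of ribonucleotide reductase, rose by 3.06 ± 0.19 and thymidine kinase Tk1 by 2.35 ± 0.12. Of 24 interferon response genes 22 rose and none fell (22 and 1 adjusted over the list alone, list adjusted p = 4.85e-16). The antiviral protein Rsad2 rose by 3.85 ± 0.28 and Usp18, which removes ISG15 from proteins, by 3.42 ± 0.28. Of 23 genes of sterol synthesis and lipid handling 16 rose and 2 fell (17 and 2 adjusted over the list alone, list adjusted p = 5.89e-08). Idi1 and Cyp51, enzymes of cholesterol synthesis, rose by 1.81 ± 0.13 and 1.41 ± 0.11. These 4 lists also passed with an estimated correlation (adjusted p = 0.0391, 0.0391, 0.0362 and 0.0269). Their mean shifts within slides were 1.40 to 1.75, 0.91 to 1.06, 1.58 to 1.81 and 0.55 to 0.95.

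**Figure D1:**
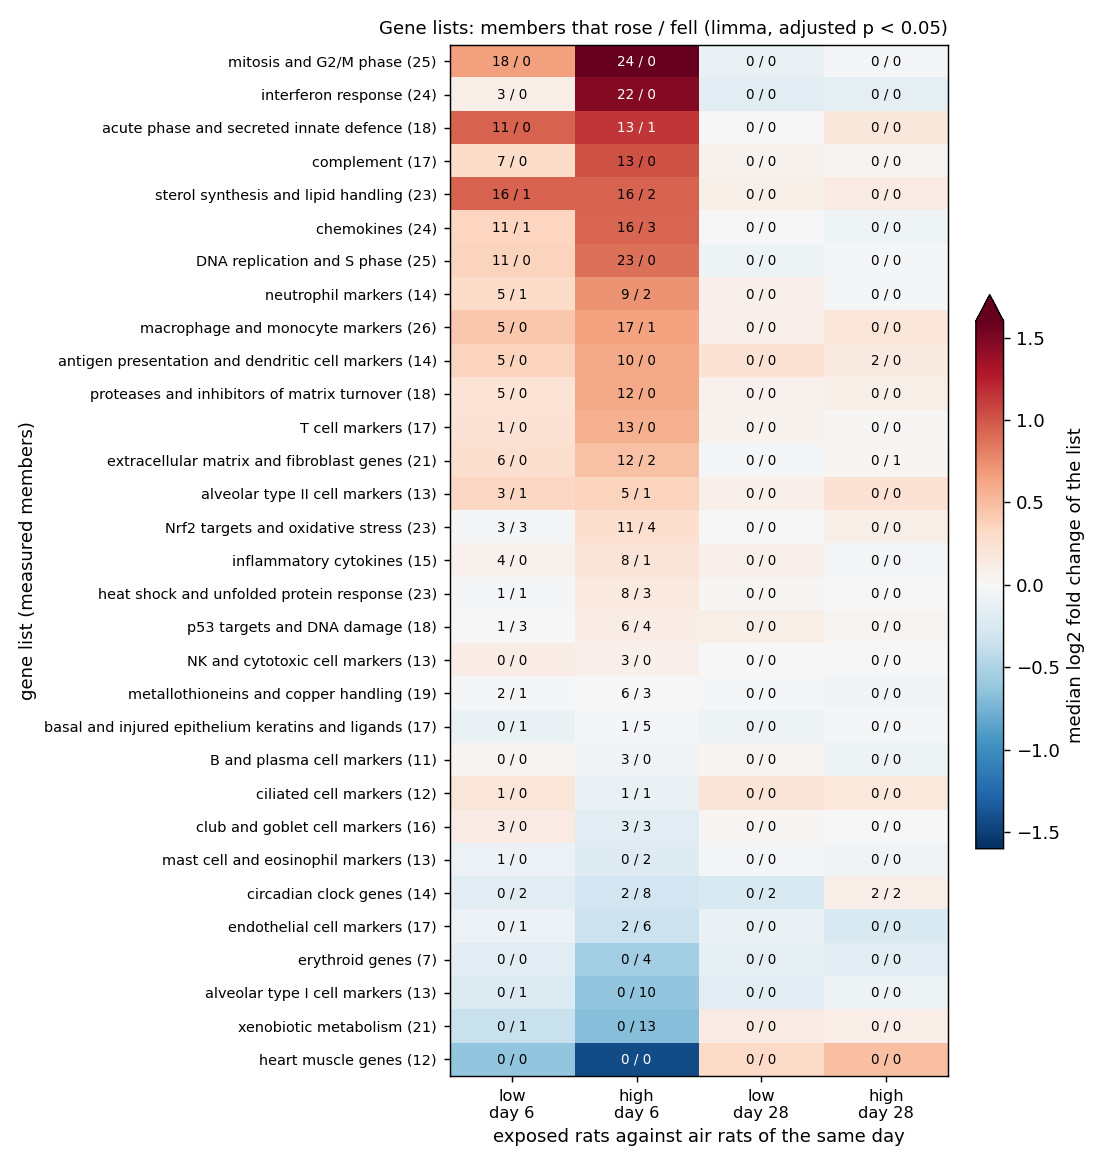
The plot gives, for the 31 gene lists, the median log2 fold change of the measured members against air at both doses and both days. The mitosis, interferon and acute phase lists had medians of 1.63, 1.47 and 1.15 at the high dose on day 6, and alveolar type I markers one of -0.63.

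Stress and metabolism genes split at the high dose on day 6. Nrf2 targets rose as a list (11 of 23 higher and 4 lower, 11 and 5 adjusted over the list alone, list adjusted p = 0.0125, adjusted p = 0.165 with an estimated correlation). The cystine transporter Slc7a11 rose by 3.47 ± 0.27, heme oxygenase Hmox1 by 2.71 ± 0.29 and the aldo-keto reductase Akr1b8 by 1.67 ± 0.14. Metallothioneins and copper handling genes did not pass as a list by camera (6 of 19 higher and 3 lower, also adjusted over the list alone, list adjusted p = 0.609, median 0), while their mean per rat was higher by 0.25 ± 0.05 (SE; exact permutation p = 0.00794). Mt1, a metallothionein that binds copper and zinc, rose by 2.25 ± 0.22 and Cp, the copper-carrying ceruloplasmin, by 1.04 ± 0.13. Heat shock and unfolded protein genes did not shift (8 of 23 higher and 3 lower, also adjusted over the list alone, list adjusted p = 0.379). The endoplasmic reticulum gene Sdf2l1 rose by 0.89 ± 0.13 and the pseudokinase Trib3 by 0.86 ± 0.13. Targets of p53 did not shift (6 of 18 higher and 4 lower, 7 and 4 adjusted over the list alone, list adjusted p = 0.609), and their median of 0.11 turned to -0.01 with median centring. Gadd45a fell by 0.66 ± 0.10 on the log2 scale. Genes of xenobiotic metabolism fell (13 of 21 lower and none higher, 14 adjusted over the list alone, list adjusted p = 6.03e-06, adjusted p = 0.0802 with an estimated correlation). Cyp2e1 was at -1.55 ± 0.23 and aldehyde oxidase Aox1 at -1.04 ± 0.16. Circadian clock genes fell (8 of 14 lower and 2 higher, 9 and 2 adjusted over the list alone, list adjusted p = 0.00556, adjusted p = 0.051 with an estimated correlation). The repressor Nr1d1 was at -1.02 ± 0.19, while Nfil3 rose by 0.58 ± 0.10. Unstated collection times may underlie clock shifts on either day. Mean shifts by slide were 0.32 to 0.67 for Nrf2 targets, -0.99 to -0.28 for xenobiotic genes and -0.44 to -0.24 for clock genes.

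In all, 6728 of 18420 genes passed at the high dose on day 6, 3883 higher and 2845 lower (57.7% higher), and 7484 passed with slide as a block. Within the 4 slides, whose arrays also made the calls, 97.7%, 99.2%, 96.3% and 99.8% of these genes kept their direction. The balance of directions hung on the scaling: 43.6% of the calls were higher with median centring, 47.6% with Cy5 alone and 46.1% in the authors' table. Requiring at least a 1.5-fold change left 2733. Of the 31 lists 21 passed (15 up and 6 down), 7 of them with an estimated correlation, and all 21 also with slide as a block. Exact permutation of the list means per rat, adjusted over the 31 lists, called also metallothionein and copper genes (0.0123) and alveolar type II markers (0.0468). It did not call endothelial (0.0559) and heart muscle genes (0.431).

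**Figure D2:**
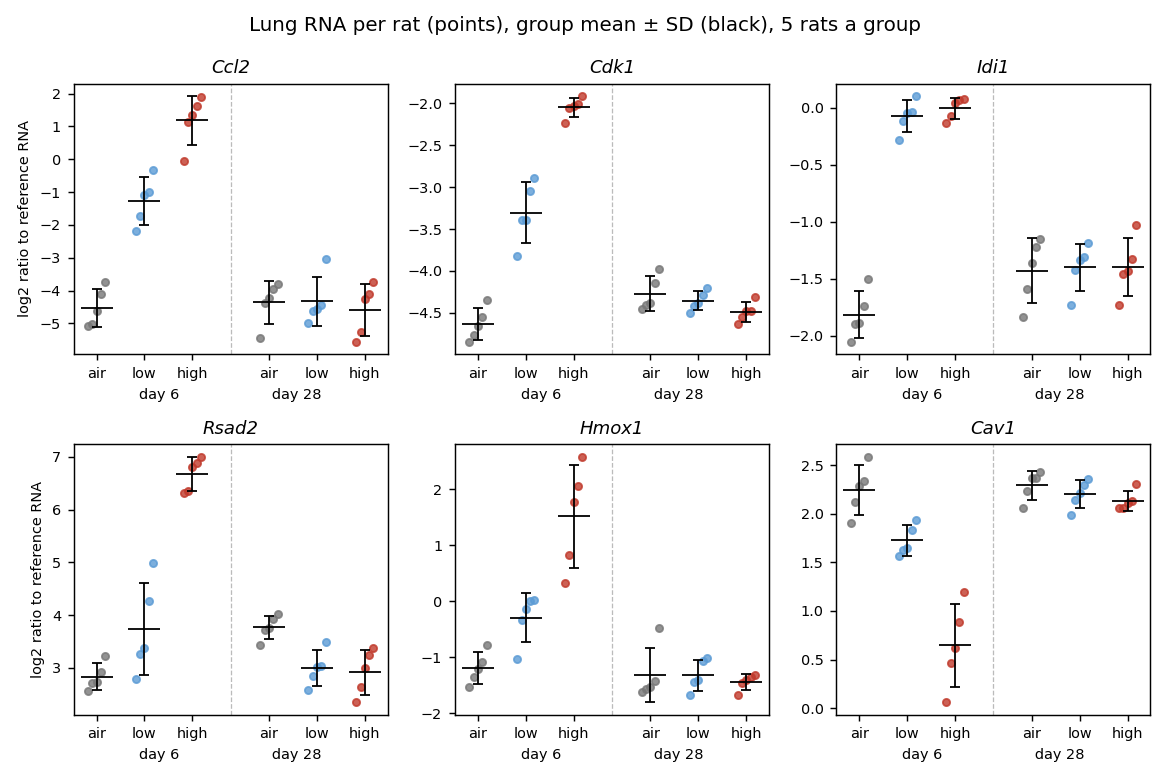
Log2 ratios to the reference RNA are drawn for each rat, with group means and SD, for Ccl2, Cdk1, Idi1, Rsad2, Hmox1 and Cav1 in the 6 groups. Idi1 was higher than in air by 1.74 at the low dose and 1.81 at the high dose on day 6, whereas Rsad2 was higher by 0.91 and 3.85.

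At the low dose on day 6 defence genes and chemokines were among the largest increases. Lcn2 rose by 4.27 ± 0.33, Defb5 by 3.74 ± 0.44, Mmp12 by 3.48 ± 0.17, Ccl17 by 3.39 ± 0.15, S100a9 by 3.31 ± 0.36 and Ccl2 by 3.25 ± 0.42 (SE, n = 5 rats per group; adjusted p = 8.37e-10, 9.78e-07, 9.5e-15, 5.11e-15, 2.78e-07 and 3.97e-06), each with all 5 exposed rats above all 5 air rats. Tac1 (-2.83 ± 0.30, and -1.04 at its second probe), Serpinb10 (-2.20 ± 0.35) and Pla2g2d (-1.53 ± 0.24) fell. The nuclear receptor Nr4a1 was at -1.30 ± 0.39 (adjusted p = 0.0382). That call ended without air rats 2, 4 or 5 (adjusted p = 0.0762, 0.0906 and 0.109) or without low dose rats 50 or 51 (0.104 and 0.136). It ended also with no filter on dim probes (0.055) and with only the compared groups in the fit (0.0535). Heme oxygenase Hmox1 was at 0.90 ± 0.29 (adjusted p = 0.061; 0.0282 with slide as a block), and Mt1 rose by 1.06 ± 0.22.

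Sterol synthesis genes rose at the low dose, with 16 of 23 genes higher and 1 lower (16 and 3 adjusted over the list alone, list adjusted p = 1.74e-17). Idi1 rose by 1.74 ± 0.13 and Cyp51 by 1.19 ± 0.11. Acute phase genes rose (11 of 18 higher, 11 adjusted over the list alone, list adjusted p = 2.31e-11), as did chemokines (11 of 24 higher and 1 lower, 11 and 2 adjusted over the list alone, list adjusted p = 1.93e-10). Neutrophil markers (5 of 14 higher and 1 lower, also adjusted over the list alone, list adjusted p = 5.31e-05) and mitosis genes (18 of 25 higher, 23 adjusted over the list alone, list adjusted p = 8.73e-22) rose as well. These 5 lists passed with an estimated correlation (adjusted p = 0.000846, 0.00171, 0.00305, 0.0266 and 0.0402), and within slides their mean shifts were 0.61 to 0.70, 0.80 to 1.20, 0.54 to 1.24, 0.59 to 0.83 and 0.63 to 0.92. DNA replication genes rose (11 of 25, 14 adjusted over the list alone, list adjusted p = 4.34e-12, adjusted p = 0.0695 with an estimated correlation). Rrm2 rose by 1.72 ± 0.19 (0.75 and adjusted p = 0.0599 at its second probe). Complement genes rose (7 of 17 higher, 8 adjusted over the list alone, list adjusted p = 7.72e-07, adjusted p = 0.0928 with an estimated correlation), C3 by 2.43 ± 0.20. Antigen presentation genes rose (5 of 14, 8 adjusted over the list alone, list adjusted p = 7.72e-07, adjusted p = 0.11 with an estimated correlation), RT1-DMa by 0.82 ± 0.13. Macrophage markers rose (5 of 26 higher, 8 adjusted over the list alone, list adjusted p = 2.58e-05, adjusted p = 0.165 with an estimated correlation), as did T cell markers (1 of 17, also adjusted over the list alone, list adjusted p = 0.000662, adjusted p = 0.187 with an estimated correlation). Cytokines rose (4 of 15, 5 adjusted over the list alone, list adjusted p = 0.0129, adjusted p = 0.127 with an estimated correlation). The mean shift of these 6 lists within slides was 0.43 to 0.56, 0.36 to 0.70, 0.30 to 0.54, 0.37 to 0.67, 0.04 to 0.47 and 0.24 to 0.34.

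Several lung tissue groups moved at the low dose on day 6. Matrix genes rose (6 of 21 higher, 6 higher and 1 lower adjusted over the list alone, list adjusted p = 0.00412, adjusted p = 0.199 with an estimated correlation). So did matrix proteases (5 of 18, 6 adjusted over the list alone, list adjusted p = 0.000811, adjusted p = 0.173 with an estimated correlation) and alveolar type II markers (3 of 13 higher and 1 lower, 4 and 1 adjusted over the list alone, list adjusted p = 0.00412, adjusted p = 0.395 with an estimated correlation). Alveolar type I markers fell as a list through 1 member past the threshold, Cav1 (-0.52 ± 0.14; 1 of 13, also adjusted over the list alone, list adjusted p = 0.00331, adjusted p = 0.258 with an estimated correlation). The call on Cav1 ended without air rats 3 or 5 (adjusted p = 0.056 and 0.0947) or low dose rat 48 (0.0611), and with median centring (0.288). Xenobiotic genes fell, Aox1 by 0.85 ± 0.16 on the log2 scale being the member past the threshold (1 of 21, 4 adjusted over the list alone, list adjusted p = 5.31e-05, adjusted p = 0.127 with an estimated correlation). Clock genes fell (2 of 14 lower, 4 lower and 1 higher adjusted over the list alone, list adjusted p = 0.019, adjusted p = 0.112 with an estimated correlation), as did basal epithelium genes (1 of 17 lower, 2 adjusted over the list alone, list adjusted p = 0.0173, adjusted p = 0.165 with an estimated correlation). Within slides the mean shift was 0.23 to 0.44 for matrix genes, 0.32 to 0.57 for proteases, 0.21 to 0.59 for type II and -0.47 to -0.08 for type I markers, -0.66 to -0.25 for xenobiotic, -0.26 to -0.05 for clock and -0.24 to -0.08 for basal genes. The interferon list did not pass (3 of 24 higher, 4 adjusted over the list alone, list adjusted p = 0.105). The calls on its members Rsad2 (0.91 ± 0.28, adjusted p = 0.0431) and Usp18 (0.93 ± 0.28, adjusted p = 0.0402) were not stable. That on Rsad2 ended without air rats 1, 2, 3 or 5 (adjusted p = 0.0881, 0.0794, 0.0672 and 0.112) or low dose rats 50 or 51 (0.153 and 0.134). That on Usp18 ended with slide as a block (0.0537), without air rats 1, 3, 4 or 5 (0.0689, 0.0555, 0.0739 and 0.108) and without low dose rats 48, 49, 50 or 51 (0.0661, 0.0607, 0.133 and 0.0778). Both ended with median centring (0.104 and 0.124), with Feature Extraction's processed signals (0.0582 and 0.0755) and with no filter on dim probes (0.0608 and 0.0574). Rsad2 failed also with no background correction (0.0531) and with only the compared groups in the fit (0.137). Usp18 failed also with Cy5 alone (0.0614), in the authors' table (0.0696), with the mean of all probes of a gene (0.0516) and at its second probe (0.0783).

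The remaining 12 lists did not pass at the low dose on day 6. Nrf2 targets (3 of 23 higher and 3 lower, 6 and 5 adjusted over the list alone, list adjusted p = 0.938) had a median of -0.02 and a mean of 0.10. Metallothionein and copper genes (2 of 19 higher and 1 lower, also adjusted over the list alone, list adjusted p = 0.995) had a median of -0.02 and a mean of 0.07. Targets of p53 (1 of 18 higher and 3 lower, 2 and 3 adjusted over the list alone, list adjusted p = 0.914) had a median of 0.003 and a mean of -0.01. The sign of the median turned with Cy5 alone for Nrf2 targets, with 4 of the other scalings for p53 targets and with median centring for B cell markers. Heat shock genes (1 of 23 higher, Sdf2l1 at 0.70 ± 0.13 and not past the threshold with median centring, adjusted p = 0.0705, and 1 lower, 3 and 5 adjusted over the list alone, list adjusted p = 0.374) and club and goblet markers (3 of 16 higher, 3 and 1 adjusted over the list alone, list adjusted p = 0.26) had few members past the threshold. So did ciliated markers (1 of 12, also adjusted over the list alone, list adjusted p = 0.123), mast cell markers (1 of 13 higher, also adjusted over the list alone, list adjusted p = 0.476) and endothelial markers (1 of 17 lower, also adjusted over the list alone, list adjusted p = 0.207; 0.022 with slide as a block). By limma 0 members passed, over all genes or over the list alone, among B cell markers (2 of 11 at an unadjusted p under 0.05, list adjusted p = 0.745), NK markers (0 of 13, list adjusted p = 0.396), erythroid genes (0 of 7, list adjusted p = 0.207) and heart muscle genes (0 of 12, list adjusted p = 0.123; 0.0367 with slide as a block). Without air rat 4, an alternative chosen after seeing the data, club and goblet and ciliated markers passed as higher at the low dose (adjusted p = 0.00103 each, medians 0.41 and 0.50), and the median of heart muscle genes turned from -0.63 to 0.52. That of xenobiotic genes went from -0.36 to -0.24 (adjusted p = 0.00194).

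Over all genes 1238 passed at the low dose on day 6, 916 higher and 322 lower (74.0% higher; 62.6% with Cy5 alone), and 1688 with slide as a block. Within slides, whose arrays also made the calls, 100%, 98.5%, 97.6% and 100% kept their direction. Median centring gave 573, array weights 3089 and a 1.5-fold minimum 539. Of the 31 lists 18 passed, 5 of them with an estimated correlation and all 18 with slide as a block. By adjusted exact permutation of the means per rat, alveolar type II markers (0.082) and xenobiotic genes (0.0724) did not pass.

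The doses differed on day 6 most of all in interferon response genes, which were higher at the high than at the low dose in 22 of 24 cases (22 adjusted over the list alone, list adjusted p = 1.81e-32; adjusted p = 0.00467 with an estimated correlation). Cxcl11, Cxcl10 and Rsad2 differed by 2.31 ± 0.12, 3.14 ± 0.27 and 2.94 ± 0.28 (SE, n = 5 rats per group; adjusted p = 8.21e-14, 6.1e-09 and 2.55e-08), and Siglec1 by 3.0 ± 0.31. Mitosis genes (23 of 25 higher, 24 adjusted over the list alone, list adjusted p = 6.24e-23) and DNA replication genes (16 of 25, 20 adjusted over the list alone, list adjusted p = 4.21e-14) were higher at the high dose. So were chemokines (11 of 24 higher and 3 lower, 12 and 4 adjusted over the list alone, list adjusted p = 2.4e-05), cytokines (5 of 15 higher and 1 lower, also adjusted over the list alone, list adjusted p = 0.000677) and Nrf2 targets (8 of 23 higher and 1 lower, 13 and 1 adjusted over the list alone, list adjusted p = 1.36e-05). Each of these 5 lists had an adjusted p = 0.0426 with an estimated correlation. Alveolar type I markers were lower at the high than at the low dose (4 of 13, 7 adjusted over the list alone, list adjusted p = 5.61e-06, adjusted p = 0.12 with an estimated correlation). Cav1 differed by -1.08 ± 0.14. Sterol genes did not differ as a list between doses (1 of 23 higher and 1 lower, also adjusted over the list alone, list adjusted p = 0.723). Idi1 differed by 0.07 ± 0.13, and the per-rat mean of the list by 0.07 ± 0.08 (SE; exact permutation p = 0.437). Ccl17 (-0.12 ± 0.15), Lcn2 (0.36 ± 0.33) and S100a9 (0.19 ± 0.36) did not pass between doses. Within slides the mean difference was 1.1 to 1.64 for interferon, 0.49 to 0.88 for mitosis, 0.34 to 0.55 for replication, 0.53 to 0.84 for chemokine, 0.24 to 0.54 for cytokine, 0.12 to 0.56 for Nrf2, -0.68 to -0.09 for type I and -0.15 to 0.26 for sterol genes.

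Of the 31 lists 19 passed between doses on day 6, 6 of them with an estimated correlation and 17 also with slide as a block. Adjusted exact permutation of the means per rat called also metallothionein and copper genes (0.0492) and p53 targets (0.0448). It did not call macrophage (0.13), T cell (0.123), antigen presentation (0.0868), ciliated (0.338) and endothelial markers (0.187) or matrix proteases (0.0614). Over all genes 2188 passed, 1476 higher and 712 lower (67.5% higher). The share was 55.9% in Feature Extraction's processed signals, 55.7% with Cy5 alone and 53.8% in the authors' table, and the count 2477 with slide as a block. The count was 1419 without high dose rat 77, 1353 without high dose rat 79, 1008 with median centring and 824 with a 1.5-fold minimum. Of the 916 genes higher at the low dose 884 were also higher at the high dose, and of the 322 lower ones 299 were also lower. Independent lists would share 193.1 and 49.7, a value that leaves out the shared air rats. Unchanged groups simulated against shared air rats shared 0 calls, a value that leaves out the effects. With the air rats split between the doses, 92.7% of the genes higher at the low dose were also higher at the high dose, and 74.5% of the lower ones were also lower. None was called in opposite directions. Of the 1183 shared genes 1072 had the larger change at the high dose and 547 passed between doses in the direction of the exposure effect; the median ratio of low to high log2 fold change was 0.613. Across genes, which are not independent replicates, the effects of both doses correlated at 0.854 (0.697 with the air rats split between the doses), against 0.497 for simulated unchanged groups sharing the same air rats; the covariance was 0.124 against 0.0127.

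On day 28, after 22 days without exposure, no listed chemokine, acute phase or cell division gene passed against air at either dose (0 by limma). At an unadjusted p under 0.05 there were 2 chemokines, 4 acute phase, 2 replication and 1 mitosis gene at the high dose, and 2 chemokines at the low dose. The largest difference was in a gene of the circadian clock. Dbp, a transcription factor driven by the clock, was 6.25-fold higher than in air at the high dose (2.64 ± 0.23; SE, n = 5 rats per group; adjusted p = 5.4e-08) and lower at the low dose (-2.04 ± 0.23, adjusted p = 8.41e-06). At the high dose the clock gene Per2 was higher by 1.16 ± 0.15, and Bmal1 and Npas2, activators of the clock, were lower by -1.13 ± 0.16 and -1.01 ± 0.16. The second probes of these 2 genes gave -0.59 and -0.18 and did not pass (adjusted p = 0.0921 and 0.282). Nr1d1 was lower by -1.91 ± 0.19 at the low dose (adjusted p = 1.03e-06), and at the high dose it was at 0.80 ± 0.19 (adjusted p = 0.0592). High dose rats also had higher Duoxa1, a maturation factor of dual oxidase (0.90 ± 0.16), Srd5a1, a steroid reductase (0.70 ± 0.12; 0.35 and adjusted p = 0.248 at its second probe), and RT1-DMa (0.61 ± 0.13), and lower elastin, Eln (-1.52 ± 0.27) and Adamts9, a matrix protease (-1.0 ± 0.19). Ccl2 was at -0.22 ± 0.42, Lcn2 at 0.61 ± 0.33, Mmp12 at 0.25 ± 0.17 and Cdk1 at -0.22 ± 0.13 at the high dose, all with adjusted p above 0.05.

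**Figure D3:**
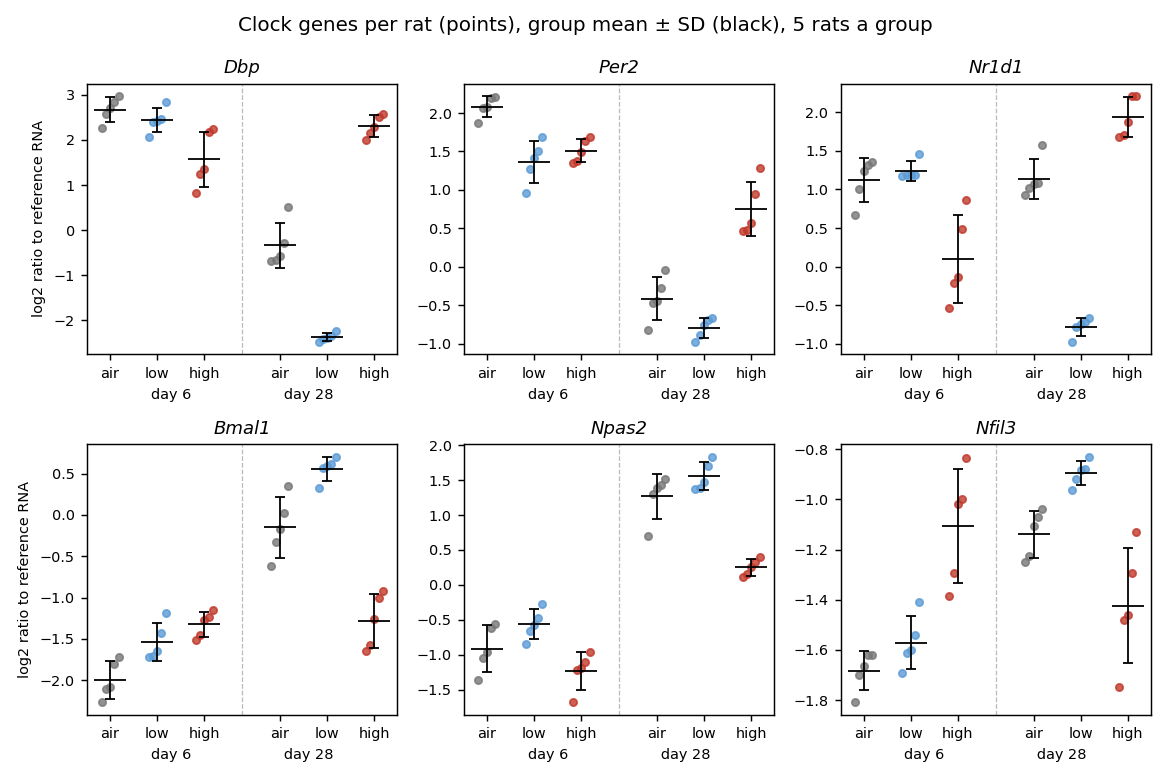
Log2 ratios to the reference RNA are drawn for each rat, with group means and SD, for the clock genes Dbp, Per2, Nr1d1, Bmal1, Npas2 and Nfil3 in the 6 groups. On day 28 Dbp was higher than in air by 2.64 at the high dose and lower by -2.04 at the low dose.

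As a list, clock genes did not pass on day 28 at the high dose (2 of 14 higher and 2 lower, 5 and 4 adjusted over the list alone, list adjusted p = 0.0794; 0.0588 with slide as a block). They fell at the low dose (2 lower, 3 higher and 7 lower adjusted over the list alone, list adjusted p = 0.001; adjusted p = 0.0485 with an estimated correlation, 0.000804 with slide as a block). Between doses they differed (6 higher and 4 lower, 8 and 4 adjusted over the list alone, list adjusted p = 1.31e-09; adjusted p = 0.000139 with an estimated correlation). Within the 3 slides with air arrays the mean shift was 0.15 to 0.37 at the high and -0.46 to -0.27 at the low dose, and within 4 slides the doses differed by 0.42 to 0.77. Antigen presentation genes passed as a list at the high dose (2 of 14 higher, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0332, adjusted p = 0.935 with an estimated correlation and 0.0538 with slide as a block). They also passed at the low dose (0 members by limma, 2 at an unadjusted p under 0.05 and 2 adjusted over the list alone, adjusted p = 0.00023, adjusted p = 0.587 with an estimated correlation). Macrophage markers were higher and endothelial markers lower as lists at the high dose (adjusted p = 0.0481 each, adjusted p = 0.935 with an estimated correlation), with 0 members past limma's threshold, 7 and 3 at an unadjusted p under 0.05, and 5 higher, 1 lower and 2 lower adjusted over the list alone. DNA replication and interferon lists were lower and the sterol list higher at the low dose (adjusted p = 0.0429, 0.0129 and 0.0477, adjusted p = 0.852 with an estimated correlation each), with 0 members past the threshold over all genes or over the list alone and 0, 4 and 2 at an unadjusted p under 0.05. The medians of DNA replication and interferon genes at the low dose turned positive with median centring (0.05 and 0.02). Mean shifts within slides at the high dose were 0.03 to 0.23 for macrophage, 0.001 to 0.14 for antigen presentation and -0.60 to -0.08 for endothelial markers, and at the low dose 0.12 to 0.24 for antigen presentation, -0.27 to 0.13 for replication, -0.48 to 0.32 for interferon and -0.15 to 0.28 for sterol genes. The other lists did not pass against air on day 28, and by exact permutation of the means per rat, adjusted over the 31 lists, none passed on that day. That adjustment needs several lists at the smallest possible p of 0.00794, which clock genes alone reached, so it could not have called them. With slide as a block 3 more passed at the high dose, interferon (lower), sterol (higher) and erythroid genes (lower; adjusted p = 0.0453, 0.0453 and 0.0295). At the low dose 5 more passed with slide as a block, macrophage markers, matrix proteases and p53 targets (higher; adjusted p = 0.0475, 0.0141 and 0.0141) and alveolar type I and erythroid genes (lower; adjusted p = 0.0141 and 0.0131). Between doses neutrophil and endothelial markers were lower as lists at the high dose (adjusted p = 0.0428 each, adjusted p = 0.629 and 0.926 with an estimated correlation), with 0 members past the threshold by limma over all genes or over the list alone (3 and 0 at an unadjusted p under 0.05) and mean differences within slides of -0.32 to -0.08 and -0.58 to 0.05.

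By limma 34 genes passed at the high dose on day 28, 14 higher and 20 lower (41.2% higher; 2 of 8 genes with median centring, or 25%), with 40 when slide was a block and 2775 at an unadjusted p under 0.05. On the 3 slides with air arrays all 34 kept their direction, which is largely fixed because the calls come from the same arrays. Across all genes, which are not independent replicates, the effects within those slides correlated with the pooled effect at 0.351, 0.566 and 0.472. Of the 34 genes 21 also passed between the 2 air groups, as did 543 of all 18420. Both comparisons hold the air rats of day 28, so a shift in those rats enters both. The count rested on single rats: it was 12, 326 and 11 without air rats 6, 8 and 9, and 59, 21, 15 and 111 without high dose rats 80, 81, 82 and 84. Left without the 4 arrays of lowest Cy5 intensity, an alternative chosen after seeing the data, 5 genes passed: Dbp (2.53), Per2 (1.06), Snx19 (0.81), Bmal1 (-1.04) and Aifm2 (-0.58), of which Snx19 and Aifm2 are outside the rule for named genes. In a fit of the 2 compared groups alone 12 genes passed, and the calls on Bmal1, Per2, Srd5a1, RT1-DMa and Adamts9 ended (adjusted p = 0.0959, 0.0508, 0.0508, 0.16 and 0.0959). With median centring the calls on Duoxa1, Srd5a1, RT1-DMa and Adamts9 ended (adjusted p = 0.132, 0.142, 0.374 and 0.0536). That on RT1-DMa ended also without air rats 6, 7 or 9 (adjusted p = 0.0873, 0.0657 and 0.117) or high dose rats 81, 82 or 83 (0.0531, 0.116 and 0.0505), and that on Adamts9 without air rats 6 or 9 (0.0519 and 0.0692) or high dose rat 81 (0.0526). At the low dose the genes past the threshold were Dbp and Nr1d1, 2 in all (1097 at an unadjusted p under 0.05, 3 with slide as a block, 6 without air rat 8). Within the 3 slides the low dose effects across all genes correlated with the pooled ones at -0.257, 0.751 and 0.824. Between doses 26 genes passed on day 28, 13 in each direction (50% higher, 22.9% of 35 with median centring), 29 with slide as a block and 17 without low dose rat 55.

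The effect of exposure shrank between the days. At the high dose 3084 genes had an effect on day 28 that differed from that on day 6, 1012 in the positive and 2072 in the negative direction (32.8% positive). The share was 46.0% in Feature Extraction's processed signals, 47.3% with Cy5 alone and 49.9% in the authors' table. The count was 3164 with slide as a block. Of the 6728 genes of day 6, 2862 had an effect that moved against its day 6 direction past the threshold. That number includes reversals, such as Dbp (-1.10 on day 6 and 2.64 on day 28). On day 28 4589 of the 6728 (68.2%) had the sign of day 6. Over all 6728 the median effect in the day 6 direction went from 0.51 to 0.08. The effect was lower by -6.16 ± 0.48 for Ccl12, by -2.81 for Cdk1 and by -2.70 ± 0.28 for C3, and higher by 1.44 ± 0.20 for Cav1. The lists of interferon response (22 of 24 lower), mitosis (23 of 25), DNA replication (17 of 25), chemokines (14 of 24 lower and 2 higher), cytokines (8 of 15), acute phase (8 of 18) and sterol genes (13 of 23 lower and 2 higher) had smaller effects, and clock genes a more positive one (7 of 14 higher and 3 lower). All passed also with an estimated correlation (adjusted p = 0.0201, 0.0208, 0.0208, 0.00726, 0.029, 0.0208, 0.0208 and 0.0208). Adjusted over the list alone, 22, 24 and 24 were lower in the first 3. By that count 16 chemokines were lower and 2 higher, 9 cytokines lower and 1 higher, and 9 acute phase genes lower. Of sterol genes 15 were lower and 2 higher, and of clock genes 9 were higher and 3 lower. Between days 359 genes differed at the low dose, 57 in the positive and 302 in the negative direction (15.9% positive; 31.4% with median centring), and 429 with slide as a block. There the sterol (13 of 23 lower), acute phase (5 of 18), chemokine (8 of 24), mitosis (11 of 25) and replication (6 of 25) lists had smaller effects also with an estimated correlation (adjusted p = 0.00146, 0.00294, 0.00394, 0.0261 and 0.0261). Adjusted over the list alone, 15, 8, 10, 20 and 15 were lower, and 1 sterol gene and 2 chemokines were higher. Of the genes called at the high dose on both days, 23 in number, 16 had 1 direction.

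Air rats themselves differed between days, which is the background of any comparison of days. Dbp and Per2 were lower on day 28 than on day 6 (-3.01 ± 0.23 and -2.50 ± 0.15; SE, n = 5 rats per group; adjusted p = 4.87e-10 and 5.27e-12), and Npas2, Bmal1 and elastin, Eln, were higher (2.18 ± 0.16, 1.85 ± 0.16 and 2.39 ± 0.27). In all 543 genes passed, 343 higher and 200 lower (63.2% higher; 23.6% with median centring), and 365 with slide as a block. The count was 213, 258, 2495, 180 and 253 without air rats 6, 7, 8, 9 and 10 of day 28, and 281, 307, 247 and 271 without air rats 1, 2, 3 and 5 of day 6. Under median centring the median of all genes moved by more than 0.1 on the log2 scale, to -0.11 between the air groups, 0.11 at the low dose on day 28, -0.15 between doses on day 28 and 0.15 for the change of the low dose effect, and changes there are relative to it.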

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

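The tests of other splits of the arrays and of the scaling of alveolar type I markers were chosen before their results were seen, and all other tests weighed here were chosen after the result was seen.

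On day 28 clock genes moved in opposite directions at the 2 doses, Dbp by 2.64 at the high and -2.04 at the low dose. If groups differed in the time of day of tissue collection, other outputs of the clock would differ too: the mean of Usp2, Wee1, Lonrf3 and Bhlhe40 was higher at the high than at the low dose by 0.269 ± 0.088 (SE; exact permutation p = 0.0238) and higher than in air by 0.245 ± 0.084 (exact permutation p = 0.0238), but their low dose mean did not differ from air past the threshold (-0.024, exact permutation p = 0.714), and Tef and Tspan4 were left out, after a first run, because their values had already been read. The mean of all 14 clock genes, activators and repressors together, lay above air at the high dose (0.23 ± 0.054; exact permutation p = 0.00794). It lay below air at the low dose (-0.363 ± 0.041; exact permutation p = 0.00794), values read before. Unless collection times differed, these signs exclude an effect in 1 direction growing with dose. Slide was excluded by a difference between doses of at least 2.732 in the mean of Dbp, Per2 and Nr1d1 on each of the 4 slides. Air rats of day 28 and day 6, which inhaled no particles, differed in the mean of the same 4 output genes by -0.687 (exact permutation p = 0.00794), most of it from Wee1 (-1.76), while Lonrf3 and Bhlhe40 did not pass (adjusted p = 0.539 and 0.208). Collection times are not stated, so a difference in them, on either day, is open but not shown. Exposure effects on the clock not ordered by dose were not tested.

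Alveolar type I markers fell at the high dose on day 6. Uniform dilution by incoming cells lacking type II markers would lower these about as much. The type II mean exceeded the type I mean in its difference from air by 1.152 ± 0.129 (SE; exact permutation p = 0.00794). Whether those cells lack them was not tested, so dilution is not excluded. Scaling was excluded (median nearest 0 under another scaling -0.57), as was slide (mean nearest 0 within a slide -0.424). Fewer type I cells and less RNA per cell were not told apart.

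Interferon response genes were higher at the high than at the low dose on day 6. A few rats did not carry this, as all 5 high dose rats lay above every low dose and air rat of that day. The list rose more than macrophage and monocyte markers did, by 1.049 ± 0.224 (SE, exact permutation p = 0.00794). Slide was excluded, the lowest difference within a slide being 1.101. The list also rose more than each of 6 other leukocyte lists, by at least 1.139 ± 0.178 over T cell markers (exact permutation p = 0.00794), which excludes a gain of any 1 of them alone in that proportion. Cells without a list here were not tested.

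Each count was set beside up to 100 splits of the same arrays that mix the groups, with the real one included. For the high dose on day 6 (6728 genes) 1 split reached the count, the real one, and the highest other gave 2989; for the low dose on day 6 (1238) it was 1 and 331, between doses on day 6 (2188) 1 and 1085, and for the change of the low dose effect (359) 1 and 319. For the change of the high dose effect (3084) 2 splits reached the count, the highest other giving 3423, and between air groups (543) 2, the highest other giving 1697. On day 28 4 splits reached the high dose count of 34 and 3 the low dose count of 2, with highest others of 2115 and 2495, and 7 reached the 26 genes between doses, with a highest other of 3119. By the number of splits alone, at fewer than 5 in 100, a grouping by chance was excluded for all but the 26 genes between doses on day 28. Splits that call many times the real count point to a structure of the arrays other than dose. On day 28 the largest for the high dose grouped air rats 7 and 8 with high dose rats 81, 82 and 83, and that for the low dose air rat 8 with low dose rats 52, 53, 55 and 56. Between doses it grouped low dose rats 53, 54 and 55 with high dose rats 80 and 84, and between air groups air rat 8 with air rats 1, 2, 3 and 5 of day 6. The gaps in Cy5 intensity between the 2 sides were 0.453, 0.499, -0.296 and 0.384 on the log2 scale, against 0.297, 0.269, 0.028 and -0.387 in the real groupings. The split with 3423 genes kept the day 6 rats in their real groups and mixed only those of day 28. It therefore still carries the day 6 effect, and its gap in Cy5 intensity, 0.031, is over day 28 rats alone. The split with 319 genes also left both day 6 groups whole, with their labels exchanged. For the counts of 34 and 2 on day 28 the exclusion of a grouping by chance is weak, since other splits called far more genes.

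In each group of 5 rats the highest or lowest log2 ratio to the reference was taken as distant when its gap to the next exceeded Dixon's 95% critical value, which by chance picks out about 1 in 20 groups. Of 540 groups tested for the 90 named genes 30 were found (5.6%), and 14 of 186 for the list means; 19 rats held at least 1 distant value, and air rat 4 of day 6 held 12, the next highest number being 3. Each value stands beside the mean of the other 4 rats of its group. In air rat 4 of day 6 the genes were Actc1 at 5.73 against 0.87, Cfi at -0.61 against -2.02, Cox8b at 6.87 against 4.12, Ctsh at 1.11 against 2.0, Cyp2e1 at 2.46 against 3.20, Esm1 at 0.84 against 2.46 and Muc20 at 0.67 against 0.17. In the same rat the list means were acute phase and secreted innate defence at 0.49 against 0.04, club and goblet cell markers at 4.16 against 2.37, ciliated cell markers at 3.03 against 1.86, xenobiotic metabolism at 2.47 against 1.89 and heart muscle genes at 4.71 against -0.75. In other air rats of day 6 they were Cp 1.57 in rat 5 against 1.16, Cyp51 -1.98 in rat 1 against -1.82, Mmp7 -0.08 in rat 2 against -0.40 and mast cell and eosinophil markers -0.79 in rat 1 against -1.21. In low dose rats of day 6 they were Ccl12 5.22 in rat 50 against 3.14, Defb5 1.52 in rat 48 against 5.34, Ifi27l2b 2.72 in rat 50 against 1.08 and Nr1d1 1.46 in rat 49 against 1.18. Also there, they were chemokines 1.64 in rat 50 against 1.21, B and plasma cell markers -1.25 in rat 51 against -0.89, mast cell and eosinophil markers -0.90 in rat 48 against -1.27 and sterol synthesis and lipid handling -0.37 in rat 51 against -0.24. Also there, they were xenobiotic metabolism 2.0 in rat 49 against 1.59 and heart muscle genes 2.07 in rat 49 against -0.81. In high dose rats of day 6 they were Klrk1 0.70 in rat 76 against 1.61 and Slc26a4 3.66 in rat 76 against 4.25. In air rats of day 28 they were Hmox1 -0.47 in rat 10 against -1.54, Npas2 0.70 in rat 10 against 1.41 and Nr1d1 1.58 in rat 10 against 1.02. Also there, they were Tgfbi -1.52 in rat 8 against -2.24 and mast cell and eosinophil markers -1.37 in rat 8 against -0.70. In low dose rats of day 28 they were Ccl2 -3.05 in rat 53 against -4.65, Cox8b 3.22 in rat 52 against 4.25 and Hbegf -0.86 in rat 54 against -0.53. Also there, they were RT1-DMa 0.63 in rat 54 against 1.09, Tac1 0.67 in rat 55 against 1.79, Usp18 1.0 in rat 52 against -0.53 and heart muscle genes 1.13 in rat 54 against -0.90. In high dose rats of day 28 they were Cav1 2.31 in rat 83 against 2.09, Mmp7 -0.12 in rat 81 against -0.35, Orm1 0.56 in rat 80 against 0.02 and RT1-DMa 1.49 in rat 82 against 1.08.

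A difference between the effects of exposure on day 28 and on day 6 was tested as an interaction in the same limma fit, for named genes, and by camera at the preset correlation, for lists, at an adjusted p under 0.05. It was found for 78 of the 90 named genes at the high dose and 37 at the low dose, and for 19 and 15 of the 31 lists. Over all genes it was found for 3084 of 18420 at the high dose and 359 at the low dose. Many named genes were chosen for their changes on day 6, which by itself favours a smaller effect on day 28. With an estimated correlation 8 and 5 lists passed, and with slide as a block 18 and 11 of the 19 and 15. Lost with the block were heart muscle genes at the high dose (adjusted p = 0.0576), and at the low dose T cell markers (0.0501), antigen presentation markers (0.0511), matrix proteases (0.103) and heart muscle genes (0.0692). Without air rat 4 of day 6 heart muscle genes did not pass at either dose (adjusted p = 0.206 and 0.689), their median going from 1.86 to 0.51 at the high and from 1.05 to -0.16 at the low dose, and matrix proteases did not pass at the low dose (0.0994). Club and goblet markers passed there at the low dose as lower on day 28 (0.00202, median -0.43 in place of -0.07). The median of xenobiotic genes at the high dose went from 0.71 to 0.45 and passed (6.35e-06). Values are log2 differences. In Mmp7, Orm1, Cxcl11 and Muc20 the signal of at least 1 air group, and in Tac1 that of high dose rats on day 6, was not well above background on any array, so the sizes of their differences are uncertain. Effects of the high dose were lower on day 28 than on day 6 in the genes Ccl12 (-6.16), Ccl2 (-5.93), Ccl7 (-5.60), Cxcl10 (-4.84), Defb5 (-4.77), Ifi27l2b (-4.77), Rsad2 (-4.69), S100a9 (-4.35), Slfn4 (-4.27), Lcn2 (-4.02), Mmp12 (-3.79) and Prss30 (-3.48). Slc7a11 (-3.47), Usp18 (-3.47), Ccl17 (-3.37), Cxcl1 (-3.37), Rrm2 (-3.30), Mmp7 (-3.29), Slc26a4 (-3.27), Spp1 (-3.11), Orm1 (-3.04), Siglec1 (-3.0), Cdca3 (-2.87) and Hmox1 (-2.83) also had lower effects. Cdk1 (-2.81), Cxcl11 (-2.71), C3 (-2.70), Eln (-2.59), Tk1 (-2.56), Il1r2 (-2.50), Cfi (-2.09), Cthrc1 (-2.04), Bmal1 (-1.80), Tgfbi (-1.80) and Mt1 (-1.78) did too. Idi1 (-1.77), Ctsh (-1.66), Icos (-1.58), Akr1b8 (-1.53), Cyp51 (-1.41), Cp (-1.39), Cldn10 (-1.37), Blnk (-1.27), Tekt2 (-1.25), RT1-DMa (-1.06), Klrk1 (-1.01) and Duoxa1 (-0.91) did too. Sele (-0.89), Nfil3 (-0.86), Ctsw (-0.84), RT1-DMb (-0.82), Osm (-0.80), Muc20 (-0.79), Sdf2l1 (-0.76), Npas2 (-0.70), Cd2 (-0.67) and Trib3 (-0.64) did too. Effects of the high dose were higher on day 28 than on day 6 in the genes Dbp (3.75), Serpinb10 (3.70), Pla2g2d (2.68), Cxcr1 (2.64), Tac1 (2.59), Cox8b (2.47), Esm1 (2.22), Nr1d1 (1.82), Nr4a1 (1.77), Cyp2e1 (1.75) and Per2 (1.74). Cyp4b1 (1.53), Cav1 (1.44), Tppp3 (1.26), Etv5 (1.25), Gata2 (1.14), Flt1 (0.72), Aox1 (0.71), Hbegf (0.52), Tp63 (0.51) and Gadd45a (0.46) also had higher effects. The second Tp63 probe, at 0.19 on day 6 and -0.19 on day 28, passed on neither. List effects of the high dose were lower on day 28 than on day 6 in the lists (median) interferon response (-1.57), mitosis and G2/M phase (-1.54), chemokines (-1.07), acute phase and secreted innate defence (-1.0) and DNA replication and S phase (-1.0). Complement (-0.85), sterol synthesis and lipid handling (-0.69), T cell markers (-0.59), macrophage and monocyte markers (-0.57) and neutrophil markers (-0.56) also had lower effects on day 28. Proteases and inhibitors of matrix turnover (-0.50), antigen presentation and dendritic cell markers (-0.47), extracellular matrix and fibroblast genes (-0.46), inflammatory cytokines (-0.43) and Nrf2 targets and oxidative stress (-0.26) did too. List effects of the high dose were higher on day 28 than on day 6 in the lists (median) heart muscle genes (1.86), xenobiotic metabolism (0.71), alveolar type I cell markers (0.49) and circadian clock genes (0.39). Effects of the low dose were lower on day 28 than on day 6 in the genes Lcn2 (-4.12), Defb5 (-3.70), Ccl17 (-3.38), Mmp12 (-3.33), S100a9 (-3.24), Ccl2 (-3.22), Ccl12 (-3.0), Ccl7 (-2.98), Orm1 (-2.57), Slc26a4 (-2.42) and C3 (-2.37). Il1r2 (-2.20), Slc7a11 (-2.07), Nr1d1 (-2.03), Rrm2 (-1.83), Dbp (-1.80), Cxcl10 (-1.78), Idi1 (-1.71), Spp1 (-1.71), Rsad2 (-1.68) and Cxcl1 (-1.62) also had lower effects. Cdca3 (-1.52), Ifi27l2b (-1.49), Tk1 (-1.46), Cfi (-1.44), Cdk1 (-1.41), Cthrc1 (-1.37), Cyp51 (-1.06), Tekt2 (-1.06), Cp (-0.89), Duoxa1 (-0.85) and Sdf2l1 (-0.68) did too. Effects of the low dose were higher on day 28 than on day 6 in the genes Serpinb10 (2.32), Tac1 (1.90), Pla2g2d (1.44), Hbegf (0.60) and Gadd45a (0.51). List effects of the low dose were lower on day 28 than on day 6 in the lists (median) acute phase and secreted innate defence (-0.74), mitosis and G2/M phase (-0.74), sterol synthesis and lipid handling (-0.72), DNA replication and S phase (-0.50) and complement (-0.38). Macrophage and monocyte markers (-0.36), chemokines (-0.31), T cell markers (-0.23), extracellular matrix and fibroblast genes (-0.21) and interferon response (-0.21) also had lower effects on day 28. Antigen presentation and dendritic cell markers (-0.17), proteases and inhibitors of matrix turnover (-0.10) and neutrophil markers (-0.09) did too. List effects of the low dose were higher on day 28 than on day 6 in the lists (median) heart muscle genes (1.05) and xenobiotic metabolism (0.33).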

How the results depend on the processing

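The removal of 2 arrays with a distant background fit (high dose rat 81 and low dose rat 52 of day 28) and of the 4 arrays with the lowest Cy5 intensity, and the list tests without air rat 4 of day 6, were chosen after seeing the data, and all other settings before. No paired analysis was possible because no animal number is shared between groups. Under other settings 4504 of 4612 values of named genes kept their side of the threshold, and their direction where a value passed, 47 no longer passed and 61 newly passed; for lists 737 of 868 did, with 104 no longer passing, 26 newly passing and 1 reversed. That was the change of the low dose effect on heart muscle genes, which turned from higher to lower and no longer passed without air rat 4 of day 6 (adjusted p = 0.689). No gene reversed. A turned sign was counted only where a value passed. Others could turn uncounted, as heart muscle genes did at the low dose on day 6. Leaving out 1 rat kept 3514 of 3600 values of named genes, with 65 no longer passing and 21 newly passing. Counts of genes stayed within 1.5 times of those reported in 115 of 144 settings and in 90 of 110 omissions of a rat.

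Counts that moved further were, with median centring, 573 for the low dose on day 6, 8 for the high dose on day 28, 1008 between doses on day 6, 127 between air groups, and 1623 and 159 for the change of the high and low dose effects. Array weights gave 3089 for the low dose on day 6, 126 for the low dose on day 28, 5328 between air groups and 1362 for the change of the low dose effect. Feature Extraction's processed signals gave 55 and 5, and Cy5 alone 105 and 5, for the high and low dose on day 28. Fitting only the compared groups gave 12 for the high dose on day 28, 9 between doses on day 28 and 1161 between air groups. A 1.5-fold minimum, which can only remove genes, gave 2733 and 539 for the high and low dose on day 6, 19 for the high dose on day 28, 824 and 17 between doses on day 6 and day 28, 206 between air groups and 1958 for the change of the high dose effect. Without the 2 arrays the high dose on day 28 gave 21; without the 4 arrays it gave 5, between doses on day 28 15, between air groups 94 and the change of the low dose effect 190. Apart from the 1.5-fold minimum and the smaller numbers of arrays, the cause was not tested. With the air rats split between the doses, the correlation of dose effects went from 0.854 to 0.697 on day 6 and from 0.761 to 0.395 on day 28, across genes that are not independent replicates.

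Leaving out each rat in turn gave 5821 to 6478 genes for the high dose on day 6, 869 to 1442 for the low dose on day 6, 11 to 326 for the high dose on day 28, 2 to 6 for the low dose on day 28, 1353 to 2591 between doses on day 6, 17 to 24 between doses on day 28, 180 to 2495 between air groups, and 2496 to 3493 and 279 to 426 for the change of the high and low dose effects. Probes well above background on fewer than 5 of the 30 arrays were not tested.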

Other observations

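The genes in the next paragraph and the look at the background fit were chosen after the result was seen.

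Further genes with a symbol passed at the high dose on day 28 outside the rule for named genes. Higher were Snx19, a sorting nexin (0.89 ± 0.17, SE; adjusted p = 0.0188), the transcription factors Myc (0.65 ± 0.12) and Batf3 (0.52 ± 0.11), Sord, sorbitol dehydrogenase (0.51 ± 0.11), Pabir2 (0.50 ± 0.11) and Tspan4 (0.46 ± 0.09). Lower were Fam89a (-0.92 ± 0.17), the vasodilator peptide gene Adm (-0.91 ± 0.17), Smtnl2 (-0.68 ± 0.13), the phosphodiesterase Pde2a (-0.66 ± 0.12), Aifm2 (-0.58 ± 0.08, adjusted p = 0.000308), the small GTPase Rhoc (-0.55 ± 0.10), Armcx2 (-0.51 ± 0.10), the elastic fibre gene Emilin1 (-0.46 ± 0.10), Kctd3 (-0.41 ± 0.08), Leo1 (-0.40 ± 0.09) and the mitochondrial deacylase gene Sirt5 (-0.38 ± 0.08). Mfsd2a, a lipid transporter, and Gde1, a phosphodiesterase, which the rule does name, were higher by 0.84 ± 0.17 and 0.69 ± 0.13. Both calls ended with median centring (adjusted p = 0.142 and 0.326), with only the compared groups in the fit (0.16 and 0.218), without air rats 6 (0.105 and 0.0644) or 9 (0.0817 and 0.0692) and without high dose rat 82 (0.0842 and 0.0602). That on Mfsd2a ended also with array weights (0.0894) and without high dose rat 83 (0.0825).

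The fitted mean of the Cy5 background was -240.3 on the array of high dose rat 81 of day 28, and lay between -37.8 and -13.2 on all arrays but those of this rat and low dose rat 52 of day 28. The first 3 principal components of the log ratios held 41.6%, 13.8% and 8.7% of their variance.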
